A study of Homo sapiens with 2 samples.

How the data were processed

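RNA sequencing of 2 libraries was used, 1 from cells labelled MIA PaCa-2 given vehicle and 1 from cells given iMQT_020, both for 48 hours. Total RNA was extracted with TRIzol, and reads were mapped to GRCh38 with HISAT2 using Bowtie2, per the labels' protocols. StringTie and edgeR are named without version or role, per the submitters' processing notes. Read length, strand setting, the step that counted reads and whether mates were counted separately are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart.

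The authors deposited estimated counts per gene as whole numbers, with FPKM and TPM beside them, for 46427 gene rows. The form of the deposited estimated counts was tested on 1302 snoRNA genes and pseudogenes of 1 transcript with 1 to 5 counts in the vehicle library. The reads derived from FPKM and the span of the gene lay 0.05 to 1 below the count for 82.0%. The counts of these genes thus had the form of fractional estimates rounded up, and other genes were not tested. FPKM values were scaled by the authors by transcript length and sequencing depth, and TPM values were scaled by the authors to the same total in each library. A shorter deposited table repeated the FPKM of 20787 genes, those at 0.001 FPKM or more in both libraries. Columns were assigned to samples by name, with 0 columns of sample values left unassigned.

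Counts were scaled by the TMM method in edgeR 4.0.16 under R 4.3.3, giving factors of 0.998 (vehicle) and 1.00 (iMQT_020). A gene was measured with at least 50 counts in at least 1 library, which left 14805 genes. The log2 ratio of CPM, iMQT_020 over vehicle, used a prior count of 0.5. With 1 library per group no test of the treatment was possible, so genes were counted by a 2-fold rule and no p-value was computed. Exact Clopper-Pearson 95% intervals of the ratio and Wilson 95% intervals of shares cover counting error only. They treat the rounded estimates as whole reads, so they can be too narrow, and more so if mates were counted separately. A count of 0 was compared with a floor of 3 counts per library, 0.0447 CPM in the vehicle library and 0.0507 in the iMQT_020 library.

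Before the data were examined, 46 gene lists were fixed, of which 14 were primary. The median log2 ratio of each list with at least 5 measured members was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. The interval of a median is a binomial order-statistic 95% interval over members, or the range of members for the list with 5. The naming rule took SLC1A5; the 12 higher and 12 lower genes whose counting interval lay farthest from no difference; the 4 members of each primary list with the largest absolute ratio; 2 such members of any other list outside the central 95%; and the most abundant member of each list of other cell types. XIST and genes of the Y chromosome were left out of named genes. Genes named outside the rule are said to be chosen after their values were seen, and a few genes that the rule names are not reported here.

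The alternatives fixed in advance were scaling by median of ratios (the method of DESeq2 1.42.0), total counts or upper quartile, minimum counts of 10, 200 or none, a prior count of 5, a 1.5-fold rule, a rule on the counting interval, deposited FPKM and TPM on log2(value + 1) for genes at 1 or more, totals without mitochondrial and rRNA genes, protein-coding genes, and 10 or 50 expression bins. Chosen after the data were seen were a set of genes overlapping no other gene, a minimum on the mean count for histone genes and a centring of the ratio in joint bins of GC content and transcript length, 10 bins each, from the canonical transcripts of GENCODE 44, for 95.3% of measured genes. Gene positions came from the RefSeq annotation of GRCh38.p14, which matched 44698 rows. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Counts were simulated with 200 genes changed 1.5-fold to 8-fold, and a further list of genes moved by 0.3 log2, among 14610 measured. The moved list lay at percentile 100. The 2-fold rule passed 100% of 3-fold, 4-fold and 8-fold changes, 0% of 1.5-fold changes and 1 unchanged gene. The true ratio lay in 95.4% of counting intervals. The simulated counts held Poisson error only, the error that the intervals assume. They check the calculation and say nothing of variation between cultures, library preparations or read assignments.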

Results

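Messenger RNA levels were compared in cells labelled MIA PaCa-2, a line established from a human pancreatic adenocarcinoma, after 48 hours with vehicle or with iMQT_020. CDKN2A, in a segment that MIA PaCa-2 is known to have lost, was at 278 TPM (vehicle) and 208 TPM (iMQT_020). The identity of the cells is therefore uncertain, and the differences below cannot be taken as those of that line. The labels describe iMQT_020 as an inhibitor of mitochondrial glutamine transport, and the comparison asks how the transcriptome differs after exposure to it. Each treatment was represented by 1 library, so there are no replicates, no difference has a replicate check, and the treatment cannot be separated from any other difference between the 2 libraries. The libraries held 67095283 (vehicle) and 59139157 (iMQT_020) estimated counts, over 22643 and 23101 genes. Intervals given for single genes are exact 95% intervals of the ratio and cover counting error only. Protein-coding genes took 95.3% of the counts in the vehicle library (95% Wilson interval 95.3% to 95.3%) and 95.8% in the iMQT_020 library (95.8% to 95.8%).

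Lists of glycolysis genes, hypoxia-inducible factor targets, DNA replication genes and cholesterol synthesis genes had median log2 ratios between −0.46 and −0.26, iMQT_020 over vehicle. Few members were at least 2-fold lower: 2 of 23 glycolysis genes, 1 of 23 hypoxia-inducible factor targets, 0 of 42 DNA replication genes and 1 of 24 cholesterol genes. PDK1, counted in the first 2 lists, lies at the edge of the rule and was within 2-fold with total counts, upper quartile scaling or a prior count of 5. Of 40 mitosis genes, 29 had a log2 ratio above 0 and the median was 0.35, but 0 were at least 2-fold higher, and CDK1, TOP2A and UBE2C were at least 2-fold lower. The 13 measured mRNAs encoded by mitochondrial DNA had a median of 0.78, with 5 at least 2-fold higher. Targets of ATF4, a transcription factor that responds to amino acid shortage, had a median of −0.21. SLC1A5, which encodes a glutamine transporter with a mitochondrial variant, had 21128 counts in the vehicle library and 14416 in the iMQT_020 library.

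SLC1A5 lies on chromosome 19 from 46774883 to 46788594 (GRCh38). Its log2 ratio was −0.38 (−0.41 to −0.34), a 1.30-fold lower level in the iMQT_020 library, and its deposited values were 248 and 198 TPM. Of all measured genes, 18.7% had a lower log2 ratio. The counts sum the transcripts of the gene, so the variants were not separated.

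Of 14805 measured genes, 318 were at least 2-fold higher in the iMQT_020 library, 457 were at least 2-fold lower and 14030 lay between. A 2-fold rule on log2(FPKM + 1), over the 13002 genes at 1 FPKM or more, gave 48 higher and 118 lower. The added 1 draws the ratios of genes with low FPKM toward no difference, so these numbers are not directly comparable. Among 12843 protein-coding genes, 201 were higher and 330 lower. Among the 9312 genes with at least 1000 counts in a library, 30 were higher and 89 lower, and the central 95% of log2 ratios ran from −0.76 to 0.59. No test across genes was possible. The medians of gene lists were therefore described by their percentile among 10000 random lists matched on expression, as a description of these libraries. Of 43 lists with at least 5 measured members, 26 lay outside the central 95% of their random lists. Of these, 5 were on the high side and 21 on the low side. Of 100 lists drawn at random from simulated counts, 8 lay outside. The simulated counts held Poisson error and changes in randomly drawn genes. Apart from the list moved by 0.3 log2, no genes in them varied together. The 8 therefore checks the calculation and gives no rate for lists of related genes.

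**Figure D1:**
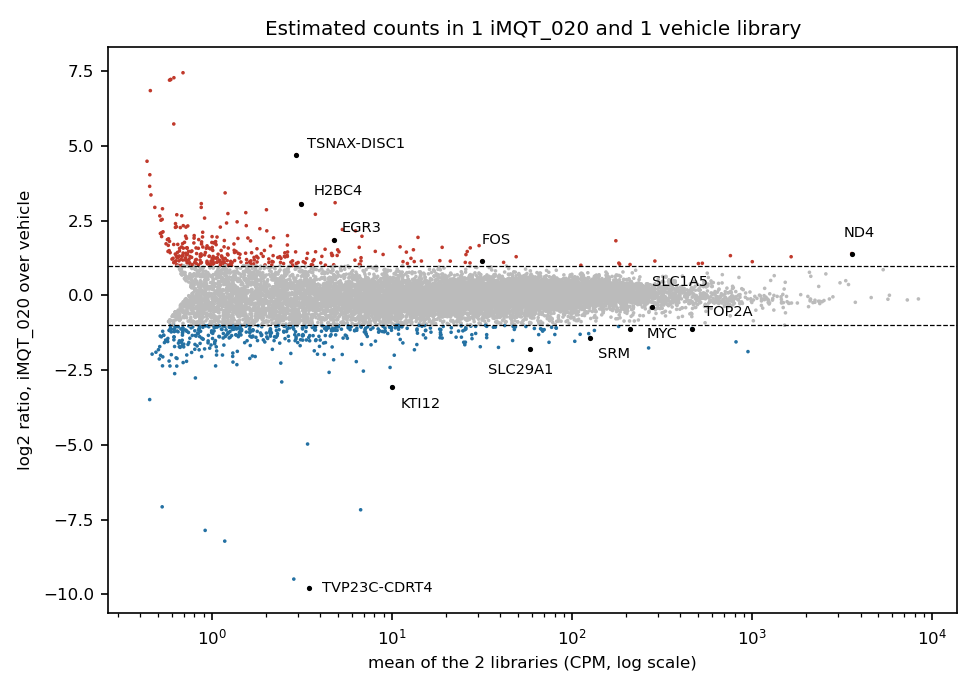
Log2 ratio of iMQT_020 over vehicle (vertical axis) against the mean of the 2 libraries in CPM (horizontal axis, log scale) for measured genes. Red points are genes at least 2-fold higher, blue points at least 2-fold lower, grey points lie between the dashed lines, and black points are named genes; the ratios of genes with few counts spread most widely.

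The ratio varied with the sequence of the transcripts. Across 14116 measured genes the median log2 ratio ran from 0.13 in the lowest of 10 bins of GC content to −0.31 in the highest, and from −0.19 in the shortest of 10 bins of length to 0.18 in the longest. Spearman's rho across genes, which are not independent replicates, was −0.34 with GC content and 0.31 with transcript length. Medians or percentiles centred on GC content and length are given beside most lists; the centring was chosen after the data were seen.

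**Figure D2:**
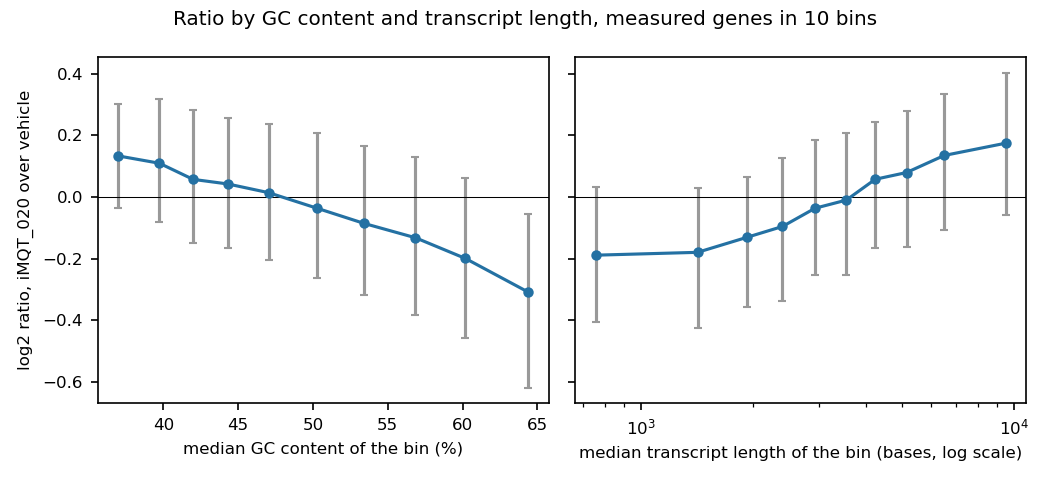
Median log2 ratio of iMQT_020 over vehicle (points) with quartiles (bars) for measured genes in 10 bins of GC content in percent (left) and of transcript length in bases on a log scale (right). The median runs from 0.13 down to −0.31 with GC content and from −0.19 up to 0.18 with length.

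All 13 measured mRNAs of the mitochondrial genome had log2 ratios above 0, 5 of them at least 2-fold higher in the iMQT_020 library (percentile 100; these genes had no value in the GC and length centring). ND4 and ND5, which encode subunits of respiratory complex I, had log2 ratios of 1.40 (1.39 to 1.41) and 1.33 (1.31 to 1.35). Mitochondrially encoded transcripts other than rRNA took 1.72% of the vehicle counts (1.71% to 1.72%) and 3.18% of the iMQT_020 counts (3.17% to 3.18%). Of the 77 nuclear genes for respiratory chain and ATP synthase subunits, 70 were below 0, none was 2-fold apart, and the median was −0.17 (−0.19 to −0.14, percentile 0). The centred median of these genes was −0.05, at percentile 3.12, inside the range of random lists, and with deposited TPM the median was −0.11 at percentile 10.4 and with deposited FPKM it lay at percentile 12.1. ATP5F1D, a subunit of ATP synthase, had the lowest ratio at −0.74 (−0.80 to −0.69), followed by UQCR11 at −0.48, and NDUFA11 and NDUFB10 at −0.47 each. The 68 mitochondrial ribosomal protein genes had a median of −0.17 (percentile 0; centred −0.04, percentile 3.16), with MRPL34 and MRPS34 at −0.53 each.

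Genes of glutamine uptake and glutaminolysis had a median of −0.14 (−0.33 to −0.00, percentile 2.45) over 22 measured members, none of them 2-fold apart and 17 below 0. The centred median was −0.19 (percentile 0.16), while with deposited FPKM and TPM the list lay at percentiles 7.42 and 6.75, inside the range. The members with the largest ratios were NADSYN1, a glutamine-dependent NAD synthetase, at −0.49, SLC25A11, the mitochondrial oxoglutarate carrier, at −0.49, SLC38A2, a plasma membrane amino acid transporter, at −0.47, and GPT2, the mitochondrial alanine transaminase, at −0.45. The 26 tricarboxylic acid cycle genes had a median of −0.08 (percentile 7.62; centred −0.00, percentile 40.5), with IDH2 at −0.45, SDHC at −0.34, OGDHL at −0.33 and OGDH at 0.29. The 16 mitochondrial chaperone and protease genes had a median of −0.07 (percentile 16.9; centred −0.08, percentile 9.32), with TRAP1 at −0.56, HTRA2 at −0.42, and DNAJA3 and LONP1 at −0.40 each. The 37 mitochondrial carriers of the SLC25 family had a median of −0.04 (percentile 34.2; centred −0.00, percentile 40.9). The 26 measured amino acid transporters had a median of −0.22 (percentile 0.9; centred −0.26), with SLC7A3 at −0.98 and SLC43A1 at −0.66, though with deposited TPM their percentile was 3.55.

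All 23 glycolysis genes were below 0, with a median of −0.40 (−0.51 to −0.28, percentile 0; centred −0.29, percentile 0.01). The lactate exporter SLC16A3 had few counts, 66 in the vehicle library and 23 in the iMQT_020 library, and a log2 ratio of −1.33 (−2.10 to −0.64). PDK1, the kinase that inhibits pyruvate dehydrogenase, had 2954 and 1306 counts (log2 ratio interval −1.10 to −0.91), ALDOA, an aldolase, was at −0.85 (−0.86 to −0.83), and PFKP, a phosphofructokinase, at −0.72. Of 23 hypoxia-inducible factor targets, 21 were below 0 and the median was −0.46 (−0.64 to −0.30, percentile 0; centred −0.40, percentile 0). Besides PDK1, these included CA12, a carbonic anhydrase, at −0.95, P4HA2, a collagen prolyl hydroxylase, at −0.89, and LOX, lysyl oxidase, at −0.88. The pentose phosphate genes, 8 measured, had a median of −0.22 (percentile 3.96; centred −0.09, percentile 18.3), and with a minimum of 10 counts it lay at percentile 2.28.

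**Figure D3:**
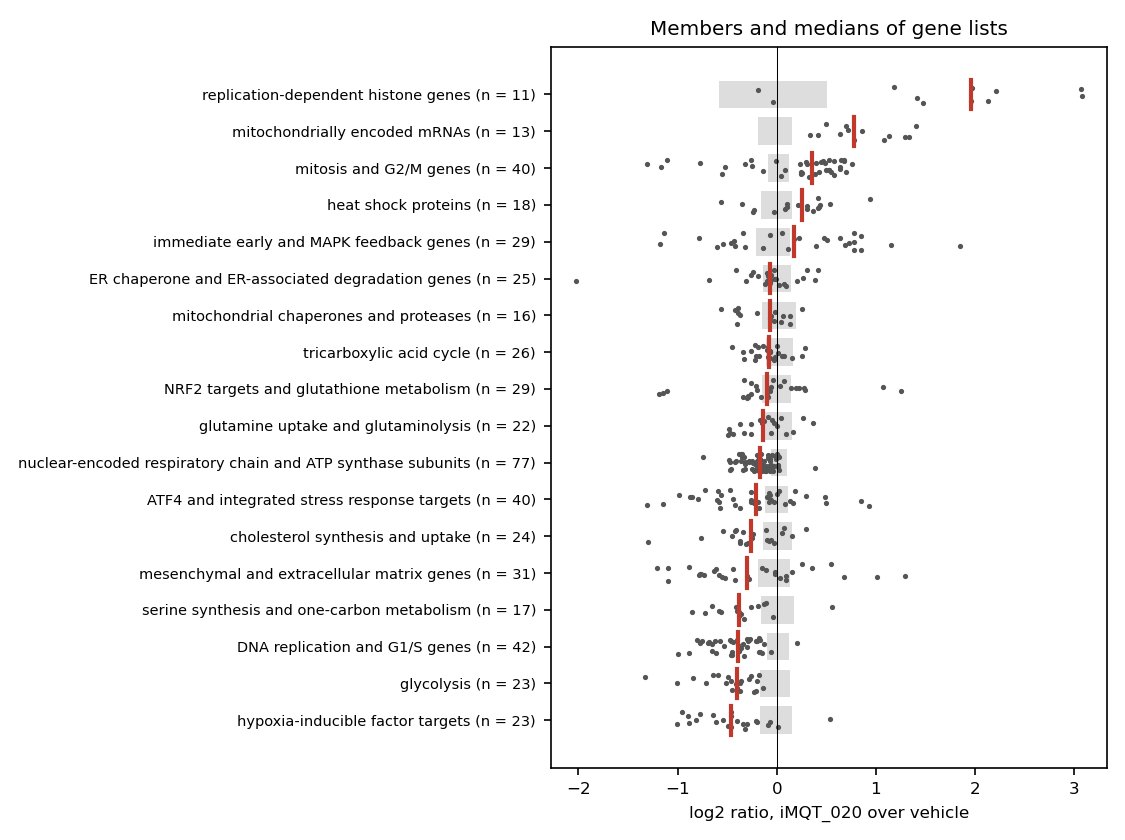
Log2 ratio of iMQT_020 over vehicle (horizontal axis) for the measured members of the primary lists and 4 further lists (grey points, spread vertically for visibility), with the list median (red line) and the central 95% of medians of matched random lists (grey bar). The medians of glycolysis, hypoxia and DNA replication genes lie to the left of 0, and those of mitosis, mitochondrially encoded and histone genes to the right. Single members can lie on the other side, as do 11 of 40 mitosis genes.

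Cholesterol synthesis and uptake genes had a median of −0.26 (−0.37 to −0.08, percentile 0; centred −0.20, percentile 0.05), with 20 of 24 below 0 and 1 at least 2-fold lower. INSIG1, a sterol-responsive regulator of SREBP processing, was at −1.30 (−1.35 to −1.25), STARD4, a sterol carrier, at −0.77, TM7SF2, a sterol reductase, at −0.54, and SQLE, squalene epoxidase, at −0.45. None of the 16 fatty acid synthesis, 17 serine and one-carbon and 22 purine and pyrimidine synthesis genes measured was 2-fold apart. Fatty acid synthesis genes had a median of −0.32 (percentile 0; centred −0.35), with SREBF1 and SCD at −0.68 each. Fatty acid oxidation genes had a median of −0.17 (percentile 2.48; centred −0.08, percentile 8.57), with CPT1B at −0.81 and ACADVL at −0.45, and were inside the range with deposited FPKM and TPM (percentiles 5.02 and 5.85). Serine and one-carbon genes had a median of −0.38 (percentile 0; centred −0.36), with SHMT2, the mitochondrial serine hydroxymethyltransferase, at −0.86 and PSAT1, a transaminase of serine synthesis, at −0.72. Purine and pyrimidine synthesis genes had a median of −0.24 (percentile 0.03; centred −0.35), with PFAS at −0.67 and TYMS at −0.65.

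Of 42 DNA replication and G1/S genes, 41 were below 0, 0 were 2-fold apart and the median was −0.39 (−0.46 to −0.30, percentile 0; centred −0.39, percentile 0). CDC45, a helicase component, had 6538 and 2893 counts (log2 ratio interval −1.06 to −0.94), TK1, thymidine kinase, was at −0.89, GINS2 at −0.80 and E2F1 at −0.77. Of 40 mitosis and G2/M genes, 29 were above 0, 0 were at least 2-fold higher and 3 at least 2-fold lower, and the median was 0.35 (0.23 to 0.50, percentile 100; centred 0.37, percentile 100). The members with the largest ratios were below 0, like the DNA replication genes: UBE2C, a ubiquitin-conjugating enzyme of the anaphase-promoting complex, at −1.31 (−1.37 to −1.24), CDK1, the mitotic kinase, at −1.17 (−1.22 to −1.12), TOP2A at −1.11 (−1.13 to −1.08) and BUB3 at −0.78. KIF4A and KIF14, kinesins chosen after their values were seen, were at 0.76 and 0.69. Cyclin-dependent kinase inhibitors and G1 cyclins had a median of −0.14 (percentile 6.91; centred −0.17, percentile 1.74).

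MYC was lower in the iMQT_020 library at −1.14 (−1.17 to −1.10), as was SRM, spermidine synthase, at −1.41 (−1.46 to −1.36). MYC targets and ribosome biogenesis genes had a median of −0.20 over 37 members (percentile 0.01; centred −0.11, percentile 0.48). Of 79 cytosolic ribosomal protein genes, 78 were below 0, with a median of −0.20 (percentile 0; centred −0.07, percentile 4.11). Immediate early and MAPK feedback genes went both ways, 17 above and 12 below 0, with a median of 0.18 (−0.34 to 0.69, percentile 99.3; centred 0.19, percentile 99.6), and with deposited TPM they lay just inside the range. With a minimum of 10 counts their median was 0.40. The transcription factors EGR3 and FOS were at 1.85 (1.57 to 2.14) and 1.15 (1.06 to 1.25), and SPRY1, a feedback inhibitor of receptor signalling, at −1.18 (−1.32 to −1.04). With deposited FPKM, EGR3 was at 0.83 and SPRY1 at −0.83, within 2-fold, and with TPM SPRY1 was at −0.89.

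Targets of ATF4 and the integrated stress response were below 0 in 30 of 40 cases, with a median of −0.21 (−0.44 to −0.07, percentile 0.02; centred −0.18, percentile 0.06). DDIT4, an inhibitor of mTORC1, was at −1.31 (−1.38 to −1.24), STC2, stanniocalcin 2, at −1.15 (−1.26 to −1.04; −0.92 with deposited FPKM), NUPR1 at −0.99 (−1.33 to −0.66) and KLHL24 at 0.93. The 25 chaperone and degradation genes of the endoplasmic reticulum had a median of −0.06 (percentile 19.4; centred −0.01), with DERL3 at −2.03 (−2.58 to −1.53; −0.81 with deposited FPKM), SDF2L1 at −0.69, SEL1L at 0.42 and CRELD2 at −0.41. NRF2 targets and glutathione genes had a median of −0.10 over 29 members (percentile 9.97; centred −0.02), 2 at least 2-fold higher and 3 lower. HMOX1, heme oxygenase, was at −1.14 (−1.21 to −1.08), and OSGIN1 at 1.25 (0.71 to 1.83; 0.70 with deposited TPM), AKR1C1 at −1.19 (−1.97 to −0.49) and AKR1C2 at −1.10 (−1.91 to −0.38; −0.98 with a prior count of 5) had fewer than 100 counts in each library. AKR1C1 and AKR1C2 are close paralogs whose reads are hard to separate.

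Mesenchymal and extracellular matrix genes had a median of −0.30 (−0.61 to 0.04, percentile 0.09; centred −0.28, percentile 0.03), with 21 of 31 below 0, 2 at least 2-fold higher and 3 lower. With a minimum of 200 counts the median was −0.53. SNAI2 and TWIST2, transcription factors of mesenchymal cells, were at −1.09 (−1.15 to −1.03) and −1.10 (−1.32 to −0.88; −0.88 with deposited FPKM and −0.96 with TPM), S100A4 at −1.21 (−1.56 to −0.89), and CCN2, a matricellular protein gene, at 1.30 (1.22 to 1.38).

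The largest ratios belonged mainly to genes with few counts or with gene models that overlap others. TVP23C-CDRT4, a read-through gene on chromosome 17, had 466 counts in the vehicle library and 0 in the iMQT_020 library, at least 137-fold lower against a floor of 3 counts (the exact interval of its log2 ratio reached −6.80, a smaller difference, as for the other genes at 0), while CDRT4, chosen after its values were seen, had 66 and 387. PRR5-ARHGAP8 was at least 113-fold lower, BIVM-ERCC5 at least 46.6-fold and CNTF at least 36.3-fold. CNTF had 123 and 0 counts, while ZFP91-CNTF, the read-through gene that contains it, had 83 and 238. UBE2F-SCLY was at −7.17 (−8.93 to −6.07) and ATRIP-TREX1 at −4.97 (−5.99 to −4.21). KTI12, UTP14C, DISC1, CZ1P-ASNS, SLC9A3 and HAGHL were between −3.06 and −2.21, though DISC1 was at −0.80 with deposited FPKM. Listed at 0 in the vehicle library were TTN, ELAPOR1, ABHD14A-ACY1, CFAP57, LINC01410 and GPR75-ASB3, between 20.3-fold and 30.9-fold higher at the least. TSNAX-DISC1 had 14 and 337 counts, at 4.71, while DISC1, a component of it, had 514 and 76. MOBP was at 4.49 (2.89 to 7.91), GALNT3 at 3.65 (2.37 to 5.75), C1orf116 at 3.43 (2.66 to 4.43), the histone gene H2BC4 at 3.07 (2.63 to 3.58) and TCTE1 at 2.87 (2.35 to 3.48). Of 94 measured read-through genes, 31.9% were at least 2-fold apart, against 11.9% of expression-matched genes that overlap no other. All 30 of those 2-fold apart were within 2-fold once their counts were summed with those of their component genes. The component genes often held most of the summed counts. A ratio of 1 gene model at such a locus is therefore not a ratio of the whole locus.

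The same rule applied to genes overlapping no other gene, a choice made after the data were seen, named well-covered genes that were lower in the iMQT_020 library. SLC29A1, an equilibrative nucleoside transporter, had 6066 and 1546 counts (−1.80, −1.88 to −1.72). CRABP2, a retinoic acid binding protein, was at −1.57 (−1.64 to −1.50) and TRIR at −1.53 (−1.59 to −1.48). Less abundant genes were CORO6 with 1104 and 244 counts, SLC22A31 at −2.26 (−0.87 with deposited FPKM), MAPK15 at −1.97 and UPK3BL2 at −1.64. On the higher side were the histone genes H2BC11 at 3.08 (2.26 to 4.13) and H2BC21 at 2.17 (1.91 to 2.43), GPR179 at 2.74, PILRA at 2.67, MGAM at 2.47 and LRRC66 at 2.34, each with under 200 counts in the vehicle library.

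Genes used to tell cell lines apart were read in both libraries. CDKN2A on chromosome 9 (21967752 to 21995324) was at 278 TPM in the vehicle library and 208 TPM in the iMQT_020 library, and its neighbours MTAP (21802636 to 21941115) at 33.7 and 26.2 TPM and CDKN2B (22002903 to 22009313) at 8.04 and 13.5 TPM. MIA PaCa-2 is known to have lost this segment from both copies of the chromosome. CD44, abundant in MIA PaCa-2, was at 0.0964 and 0.0209 TPM, and ANXA1 at 3.13 and 2.74 TPM. NEFL was at 37.9 and 35.4 TPM, LIN28B at 31.0 and 37.3 TPM and PAX2 at 2.09 and 1.90 TPM. IRS4, an insulin receptor substrate associated with the HEK293 line, was chosen after its values were seen. It was at 521 and 148 TPM, a log2 ratio of −1.88 (−1.90 to −1.86).

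**Figure D4:**
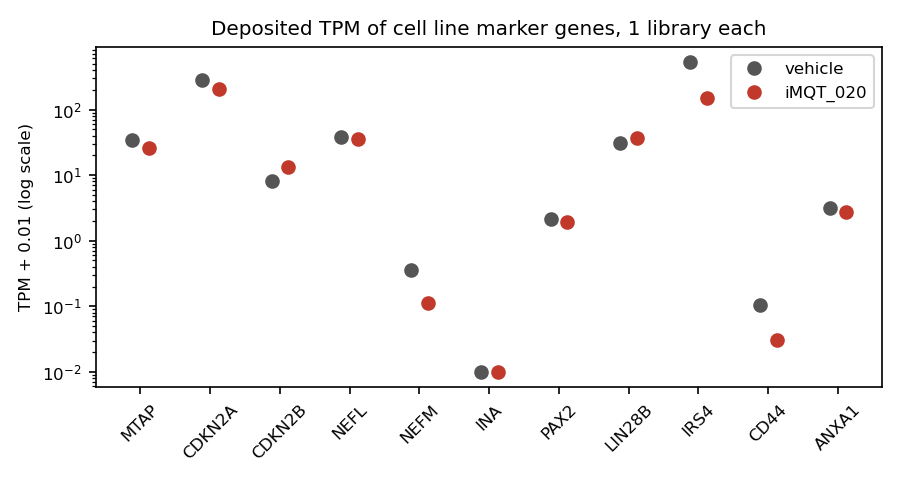
Deposited TPM plus 0.01 (vertical axis, log scale) of genes that differ between cell lines, in the vehicle library (grey) and the iMQT_020 library (red), 1 library each. The 9p21 genes MTAP, CDKN2A and CDKN2B are above 8 TPM in both libraries and CD44 is below 0.1 TPM.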

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

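The set of genes overlapping no other gene and the GC and length centring were chosen after the data were seen. Scaling by median of ratios, total counts or upper quartile, a prior count of 5 and totals without mitochondrial and rRNA genes kept the numbers of higher and lower genes within 1.5 times of 318 and 457. Centring on GC content and length gave 266 higher and 307 lower, also within 1.5 times, with a larger fall on the lower side. The ratios of single genes in the text are not centred. The numbers moved further under other settings. They were 1236 higher and 1008 lower with a minimum of 10 counts, 3503 and 2756 with none, and 89 and 244 with a minimum of 200. A 1.5-fold rule gave 933 and 1514, and the rule on the counting interval 136 and 181. Deposited FPKM gave 48 and 118, and deposited TPM 140 and 223. Over the smaller set of 7136 genes overlapping no other they were 147 and 213, so that 5.04% of that set was 2-fold apart. The higher count was 201 over protein-coding genes. More or fewer genes entered under other minimums and gene sets. With FPKM and TPM, the 1 added to each value draws ratios at low values toward 0, and a minimum of 1 changes the genes that enter. How much each of these accounts for was not tested. Of 467 alternative list medians, 3 were of opposite sign in lists outside the central 95%; of the rest, 456 stayed within the interval of the main median and 8 did not. A further 5 of those 456 were also of opposite sign, in lists inside the central 95%: p53 targets (0.09), NF-kB genes (0.05) and ferroptosis regulators (0.09) after centring, and leukocyte genes with a minimum of 10 counts (0.32) and with TPM (0.05). The tricarboxylic acid cycle median was −0.0036 after centring, and the nuclear respiratory chain median −0.0460 after centring and −0.1096 with TPM; the cause was not tested for TPM. The epithelial median reversed to 0.0336 with a minimum of 200 counts and 0.0137 with FPKM, and the stemness median to 0.1365 with FPKM; the cause was not tested. Of the 10 primary lists outside the central 95%, 7 stayed outside under all 10 alternatives fixed in advance; the exceptions are the glutamine, respiratory chain and immediate early lists, with FPKM or TPM. Of 762 alternative gene values, 640 stayed within the counting interval, 122 moved and 0 reversed. Of 69 named genes at least 2-fold apart, 12 were within 2-fold with FPKM or TPM and 3 under another alternative. Genes below 1 FPKM or TPM in both libraries had no value in those alternatives and could not be counted among the 12. Examples are TTN (0 TPM vehicle, 0.0292 TPM iMQT_020) and SLC16A3 (0.848 and 0.341 TPM). The authors' own fold changes were not used here, so that alternative was not run. No paired analysis was possible because each group had 1 library, and for the same reason none could be left out. Depth limited the genes with few counts, whose intervals are widest.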

Other observations

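Of 44 listed histone genes of DNA replication, whose mRNAs mostly lack a poly(A) tail, 11 were measured, 9 of them at least 2-fold higher in the iMQT_020 library and 2 below 0, with a median of 1.96 (−0.04 to 3.07, percentile 100; centred 2.24). The median was smaller in alternatives, at 1.25 with a minimum of 10 counts, 1.08 with FPKM and 0.88 with TPM, each at percentile 100. Of 25 members with 10 counts or more in a library, 14 were at least 2-fold higher and 1 lower, and of 8 with a mean of at least 50 counts, a choice made after the data were seen, 8 were higher. H2BC11 and H2BC4 were at 3.08 and 3.07. Heat shock protein genes had a median of 0.26 over 18 members (percentile 99.9; centred 0.29), with DNAJB4 at 0.94 and HSPB1 at −0.56. Structural non-coding RNAs had a median of −0.28 (percentile 2.45; centred −0.13, percentile 11.8; percentile 3.75 with a minimum of 200 counts), with MALAT1 at 1.05, just within 2-fold with FPKM, and SNHG12 at −0.99. Antigen presentation genes had a median of −0.27 (percentile 1.41; centred −0.17, percentile 4.23; percentile 6.17 with a minimum of 10 counts), with NLRC5 at −0.84 and HLA-F at −0.70. Stemness and drug resistance markers had a median of −0.45 over 11 members (percentile 0.885; centred −0.37, percentile 0.865), with LGR5 at −1.01 (−0.98 with a prior count of 5 and −0.53 with TPM) and CXCR4 at −0.98. Epithelial genes had a median of −0.38 over 9 members (percentile 0.9; centred −0.13, percentile 12.5, inside the range), with CDH3 at −0.82 and ST14 at −0.56; both lists changed sign in an alternative. Commonly used reference genes had a median of −0.17 (percentile 2.33; centred −0.05, percentile 26.5), with GUSB at −0.39, and lay inside the range with TPM, FPKM (percentile 11.1), 50 expression bins (4.21) and minimums of 10 (2.75) and 200 counts (2.74).

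Lists inside the range of random lists were apoptosis regulators at 0.12 (percentile 95.7), autophagy and lysosome genes at 0.03 (percentile 66.8), p53 targets at −0.02 (percentile 54.5), mTORC1 regulators at 0.02 (percentile 59.5), aminoacyl-tRNA synthetases at −0.08 (percentile 13.1), ferroptosis regulators at −0.15 (percentile 11.3, though −0.26 at percentile 0.81 with a minimum of 200 counts and −0.06 at 36.8 with a minimum of 10), NF-kB genes at −0.11 (percentile 36.4) and interferon-stimulated genes at −0.09 (percentile 41.7). After centring, apoptosis regulators lay at percentile 99.0 and cyclin-dependent kinase inhibitors with G1 cyclins at 1.74, outside the range. Of the lists of other cell types, endocrine genes had a median of −0.25 (−0.62 to 1.40, percentile 28.0) over 6 measured members. Of these, 2 were at least 2-fold higher and 0 lower, and PAX6 was the most abundant at 1249 and 924 counts. Leukocyte and blood genes had a median of −0.27 (percentile 31.3), with HBA1 at 239 and 141 counts. The acinar list had 2 measured members, led by AMY2B at 100 and 127 counts, the fibroblast and endothelial list 4, led by COL1A1 at 2797 and 1624 counts, and the metallothionein list 2.

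In the explanations weighed here, both tests of read-through genes were chosen after results at such genes were seen, and the GC and length centring after the data were seen. The reads of CDKN2A go against the known loss of 9p21 in MIA PaCa-2. MTAP, lost with it in that line, was at 33.7 TPM at most and 26.2 TPM at least, which argues against reads of another locus assigned to CDKN2A alone and is consistent with cells that carried the segment. A minor share of another line among MIA PaCa-2 cells would leave CD44 and ANXA1 abundant, yet the higher of them reached 3.13 TPM. The HEK293 line as the origin stays open, since 3 of 5 genes associated with it were at 1 TPM or more in both libraries. These were NEFL, LIN28B and PAX2, but not NEFM or INA. IRS4, also associated with that line, was at 521 TPM (vehicle) and 148 TPM (iMQT_020). It was chosen after its values were seen and was not counted among the 5. No biological explanation of the differences between the 2 libraries was tested, and the identity of the cells would need a genotype.

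The excess of large ratios among read-through genes may come from reads moved between gene models that share a locus. The share at least 2-fold apart was 2.69 times that of expression-matched genes overlapping no other, between the 1.5 and 3 set as bounds. In 14 of the 30 read-through genes at least 2-fold apart the component genes together moved the other way, but only in 5 did the difference exceed 18.8% of the component counts, the usual spread of a gene, so their own variation could set the sign elsewhere. The 14 met the bound set against this explanation; the condition on spread was added after the 14 was known, and in 4 of those 5 the component genes moved the other way. Reassigned reads and a difference in read-through transcription between the libraries cannot be told apart from these counts.

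A trend of the ratio with GC content and transcript length could produce list medians away from 0. Of 10 primary lists outside the central 95%, 9 stayed outside on the same side after centring, and the mitosis list stayed at percentile 100, which argues against the trend as the whole cause for these. Of 15 other lists outside the central 95% with a centred value, 8 stayed outside on the same side; those that did not were the mitochondrial and cytosolic ribosomal protein, fatty acid oxidation, antigen presentation, epithelial, structural non-coding RNA and reference gene lists. For the nuclear respiratory chain genes the centred median was at percentile 3.12 (−0.05 against −0.17 before), consistent with the trend as a source of that difference. The treatment stays among the open explanations for all of these lists, since with 1 library per group it cannot be separated from library preparation or culture.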
